A study of Mus musculus with 6 samples.

How the data were processed

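The 6 libraries were 3 of NCTC 1469 cells at normal gravity and 3 of cells on a random positioning machine, each after 6 days, as the labels state. Per the labels' protocols the cells grew in DMEM with 10% fetal bovine serum at 5% CO2 and 37 degrees, RNA was taken up in Trizol, and an mRNA library kit was applied to 1 µg of total RNA. Per the submitters' processing notes, fastp 2.0 and HISAT2 2.1.0 were used. The counting tool, its treatment of strand and of reads with several matches, the genome build and the annotation were not given in the sources used here. The deposited table holds whole-number read counts per gene, which the authors left unnormalized as far as the values show, with gene coordinates, lengths and pathway terms. Start and end of 52141 of the 53705 genes shared with GENCODE M21 (97.1%) were equal to that annotation of GRCm38, and coordinates are given in that assembly as the table lists them. The table has 53801 lines below its header, of which 1 holds no gene and was left out. The 6 count columns are named with the letter C or R and a number. They were assigned to samples by reading R as the random positioning machine and C as control, which the labels do not state. No other column of per-sample values was present.

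Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (14509 genes), libraries were scaled by TMM, and the groups were compared with the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are simulated microgravity over normal gravity, and their SE is the fold change divided by the root of the F statistic. CPM values are scaled by TMM, except those of the marker lists and of shares, which are scaled to all counts of a library. Means are given with the SD of 3 libraries. Of 32 gene lists fixed before the data were examined (16 main, 9 secondary and 7 of cell type markers), 29 had at least 5 tested genes. They were tested against the other genes with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists. The same test was applied to pathway terms of the table with 10 to 300 tested genes. Camera with an estimated correlation and fry were alternatives, and no list passed with an estimated correlation. The share of counts from mitochondrially encoded genes was compared by an exact permutation test. Counts of 0 are given with the level that 3 counts of the total allow. Such limits cover counting error only, since the counts carry no molecular identifiers. The confidence interval of an odds ratio covers the sampling of genes only, with genes taken as independent.

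The genes named were set by a rule fixed before the data were examined. It takes the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 5 CPM, groups that do not overlap and no predicted-gene, clone or pseudogene name. It adds the 2 members with the lowest p of each main list and the 1 of each other list, among those past the threshold. It always takes Ppargc1a, Cpt1a, Srebf1, Fasn, Pparg, Ppara, Cd36, Sod2, Mtnr1a and Mtnr1b, and for pathways the 5 terms with the lowest adjusted p in each direction. Lpl, Lamp2, Bhlhe40, Per2, Cyp51, Idi1, Spp1, the individual markers other than Ass1, Pdgfrb and Vwf, and the members named for the comparison without normal gravity replicate 1 or for the level of Fos were chosen after their values were seen.

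The procedure was tested on simulated data with 200 changed genes, drawn from the means, library sizes and gene-wise spread of the real libraries. For 3 against 3 (14204 genes tested) it recovered 0 of 67 genes changed 1.5-fold, 4 of 67 changed 2-fold and 46 of 66 changed 4-fold, with 1 unchanged gene called. Each gene had the same spread in every library there, so no library stood apart as normal gravity replicate 1 did. With a gene length trend put into 1 library (14223 genes tested), 0 of 67, 1 of 67 and 44 of 66 were recovered, with 3 unchanged genes called. Removing that trend gave 1, 11 and 50, with 7 unchanged genes called. Recovery in the real comparison may differ from these shares. Without normal gravity replicate 1 (14494 genes tested) it recovered 21 of 67, 48 of 67 and 56 of 66, with 12 unchanged genes called. In 30 simulated lists of 20 genes, 1 of them shifted by 0.5 log2 units, camera with the preset correlation called the shifted list and none of the others, and with an estimated correlation it called none. The simulated genes varied independently of each other. In the real lists the estimated correlation ran from -0.149 for endothelial markers to 0.892 for cytosolic ribosomal protein genes. The simulation therefore cannot tell how often the preset correlation calls an unchanged list of correlated genes.

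Alternatives fixed before the data were examined were DESeq2 size factors in place of TMM, scaling by library size alone, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a test against a fold of 1.5, the replicate number as a block, counts thinned to the smallest library, leaving out mitochondrially encoded genes, and leaving out each library in turn. After seeing the data, 3 were added: limma-voom with library quality weights, a trend on gene length removed from each library, and trends on gene length and GC content removed. No 2 libraries agreed within sampling noise, the closest pair having a chi-square of 15.5 per gene.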

Results

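RNA sequencing measured polyadenylated transcripts in NCTC 1469 cells, a line derived from mouse liver whose samples carry the label hepatocytes and a wild-type genotype. Cells were cultured for 6 days at normal gravity or on a random positioning machine, which keeps turning a culture about its axes so that gravity has no constant direction and which stands for simulated microgravity. Each group had 3 libraries. The deposited table held raw counts for 53800 genes, with 31406875 to 32797684 counts per library at normal gravity and 30474792 to 34318208 in simulated microgravity. Between 18938 and 19311 genes had at least 1 count in a library. The title of the series names melatonin, mitochondrial dysfunction and lipid metabolism. None of the 6 samples carries a melatonin label, so the question these libraries address is which genes differ between simulated microgravity and normal gravity. The labels do not say that the replicates came from separate cultures, and p-values therefore measure the spread between these samples, which may be technical. The columns of the table carry the letters C and R with the numbers 1 to 3. R was read as the random positioning machine and C as its control, and every direction given here rests on that reading.

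One normal gravity library stood apart from the rest. Replicate 1 correlated with normal gravity replicates 2 and 3 at r = 0.936 for both across the log2 CPM (counts scaled to library size) of 14509 genes, below its correlations of 0.943 to 0.946 with the simulated microgravity libraries. Replicates 2 and 3 correlated at 0.985 and the simulated microgravity libraries with each other at 0.983 to 0.985. Its SD from the mean of the other 2 libraries of its group was 1.00 log2 units, against 0.62 for each of replicates 2 and 3 and 0.44 to 0.45 for the microgravity libraries. Genes of up to 1000 bases had a median deviation of 0.63 in replicate 1 and genes over 5000 bases one of -0.70. Ribosomal protein genes took 5.47% of its counts, against 3.18% and 3.16% in replicates 2 and 3 and 2.77% to 2.86% in simulated microgravity. Its level of the immediate early gene Fos was 166 CPM, against 20.4 and 22.5 CPM in the other 2 normal gravity libraries and 55.9 to 73.1 CPM in simulated microgravity. All 6 libraries entered the comparisons.

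**Figure D1:**
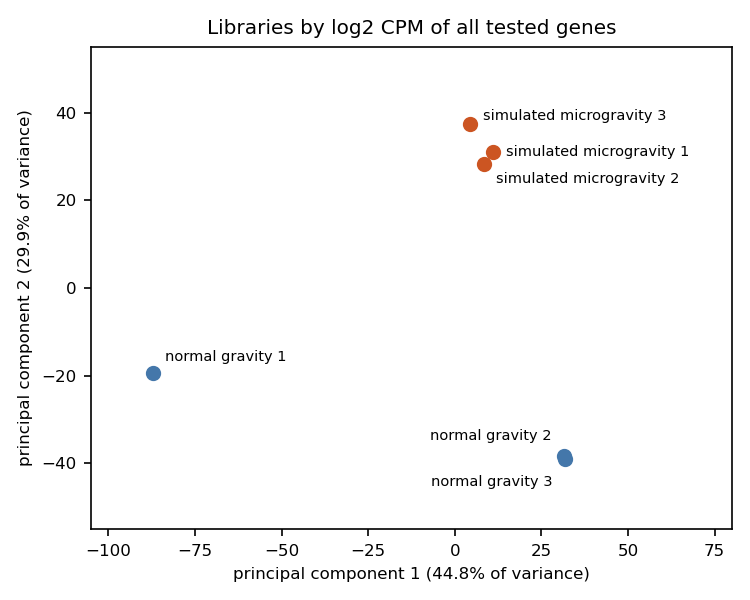
Each point is 1 library, placed by its scores on the first 2 principal components of log2 CPM over all tested genes; blue is normal gravity and orange simulated microgravity. The first component (44.8% of the variance) holds normal gravity replicate 1 at -87.2 apart from the other 5 libraries at 4.5 to 31.7, and the second (29.9%) separates the 3 microgravity libraries at 28.3 to 37.4 from the normal gravity libraries at -39.0 to -19.4.

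Simulated microgravity changed the level of 221 of 14509 tested genes, 168 upward and 53 downward. Among the genes with the largest rises, the myeloid chemokine gene Ccl6 went from 7.36 ± 3.78 CPM (SD, n = 3) at normal gravity to 104.1 ± 28.8 CPM (SD, n = 3) in simulated microgravity. Its log2 fold change was 3.82 (SE 0.42, adjusted p = 0.0155). Adgre5, which encodes the adhesion receptor CD97, rose from 37.7 ± 4.58 to 390.3 ± 16.6 CPM, a log2 fold change of 3.37 (SE 0.13, adjusted p = 0.00136). Tubb3, a beta-tubulin gene best known from neurons, rose by 3.61 log2 units (SE 0.27), the sphingosine-1-phosphate receptor gene S1pr4 by 3.13 (SE 0.27), the kallikrein gene Klk1b11 by 3.07 (SE 0.20) and Tppp3, whose product promotes tubulin polymerization, by 2.83 (SE 0.44). On the falling side, the serine protease inhibitor gene Serpina3g went from 13.8 ± 2.97 to 1.32 ± 0.29 CPM, a log2 fold change of -3.38 (SE 0.26, adjusted p = 0.0056). Cox7a2l, whose product takes part in the assembly of respiratory chain supercomplexes, had a log2 fold change of -2.59 (SE 0.33, adjusted p = 0.022), with 215.9, 105.6 and 105.7 CPM at normal gravity and at most 25.9 CPM in simulated microgravity. Macrod2, an ADP-ribose hydrolase gene, changed by -2.28 (SE 0.16), Cd5 by -2.10 (SE 0.13), the sialyltransferase gene St3gal6 by -2.09 (SE 0.20) and Olfm1 by -2.02 (SE 0.19). In the mouse assembly GRCm38, Ccl6 lies on chromosome 11 from 83587882 to 83593087, Adgre5 on chromosome 8 from 83723251 to 83741326, Serpina3g on chromosome 12 from 104236245 to 104241939 and Cox7a2l on chromosome 17 from 83501919 to 83514333.

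The median log2 fold change was 1.18 over the genes that rose and -1.56 over those that fell. 105 of the former and 34 of the latter changed by more than 2-fold. Adgre5 overlaps Ddx39, Macrod2 overlaps Flrt3 and St3gal6 overlaps Dcbld2 on the other strand, and Klk1b11 and Serpina3g belong to families of near-identical genes, so the counting could have divided their reads. The groups did not overlap for 3962 genes (27.3%). The mean share over the 10 splits of the 6 libraries into 3 and 3 is 10% by construction for genes without ties. The share in each other split was not computed, so the excess cannot be set against chance. The count of changed genes rests on the libraries entered: without normal gravity replicate 1 it was 4559 of 14809 (2329 higher and 2230 lower) and included all 221 genes with the same direction. Log2 fold changes without that library still ran with gene length (Spearman rho across genes -0.14) and GC content (0.17), against 0.19 and -0.05 with all libraries. The count was 22 and 23 without normal gravity replicates 2 and 3 and 3, 24 and 12 without simulated microgravity replicates 1, 2 and 3. Of 26 genes past the threshold that the naming rule took, 7, 6, 1, 7 and 3 passed in these 5 comparisons, and Adgre5 passed in each. The share of higher genes among the calls, 76% in the main comparison, was 51.1% without replicate 1 and 58% with DESeq2.

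**Figure D2:**
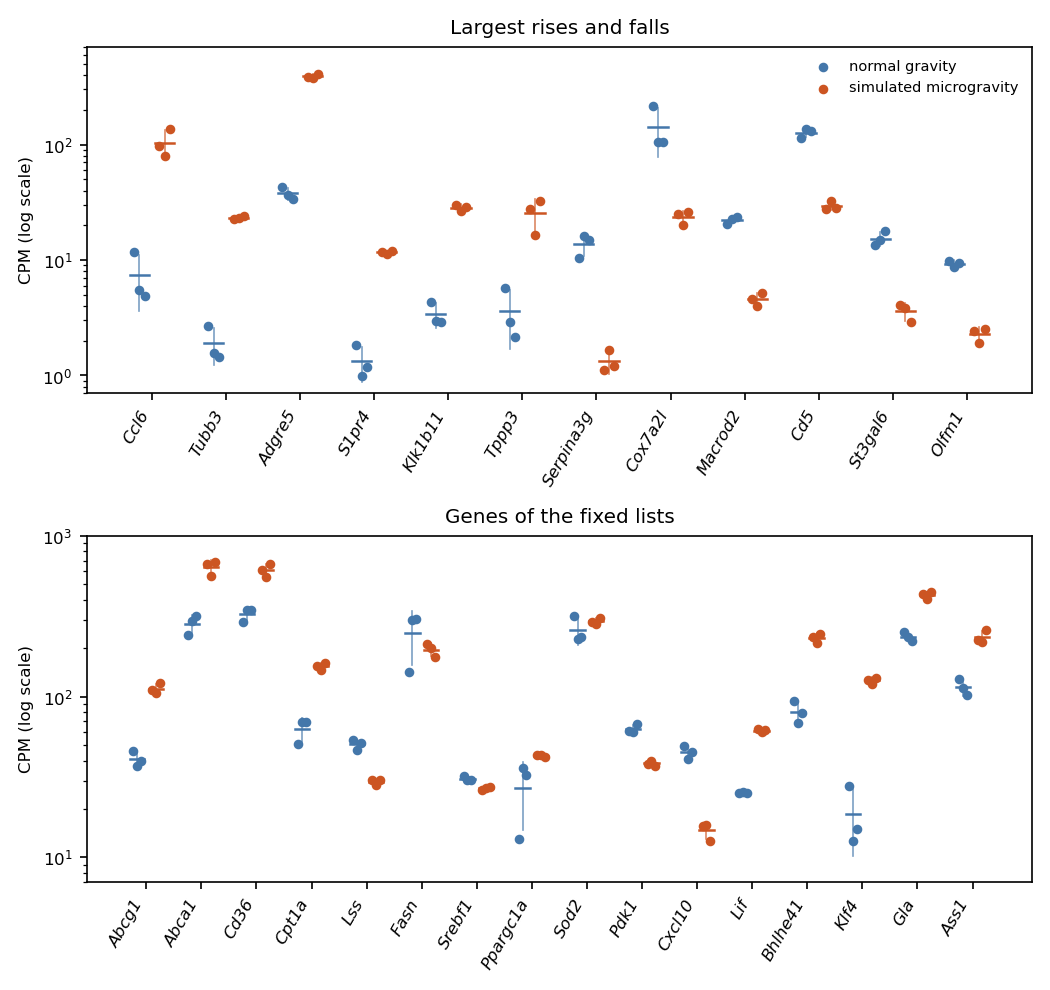
CPM on a log axis in each library (points, blue for normal gravity and orange for simulated microgravity), with the group mean (horizontal line) and SD (vertical line, n = 3), for the 12 genes with the largest rises and falls (top) and for genes of the fixed lists (bottom). Adgre5 lies near 390.3 CPM in simulated microgravity and 37.7 CPM at normal gravity, while the groups overlap for Fasn and Sod2.

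Of 22 tested genes of lipid droplets, lipolysis and lipid transport, 3 rose, 1 fell and 18 did not pass. Abcg1 and Abca1, which encode the transporters that export cholesterol to lipoproteins, rose by 1.46 (SE 0.13, adjusted p = 0.0079) and 1.17 (SE 0.15, adjusted p = 0.0205) log2 units. The fatty acid receptor gene Cd36 rose by 0.91 (SE 0.13, adjusted p = 0.0308), and the lipoprotein lipase gene Lpl fell, at -1.37 (adjusted p = 0.0381). Adjusted over the list alone, 4 were higher and 1 lower. The list as a whole ranked above the other genes in the camera test (median log2 fold change 0.22, adjusted p = 0.00408; adjusted p = 0.596 with an estimated correlation). When normal gravity replicate 1 was left out, 12 members were higher and 2 lower with a median of 0.50 (camera adjusted p = 0.00106; adjusted p = 0.407 with an estimated correlation), among them the lipid droplet coat gene Plin2 at 1.07 (adjusted p = 0.000444). Abca1 and Lss, a gene of the next list, did not pass once a trend on gene length was removed, a fit chosen after seeing the data.

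Cholesterol synthesis genes ranked below the other genes in the camera test with the preset correlation. They did not pass as a group in fry (adjusted p = 0.143, and 0.0039 without normal gravity replicate 1). All 22 tested members had a log2 fold change below 0, with a median of -0.64 (camera adjusted p = 1.66e-07; adjusted p = 0.685 with an estimated correlation). Only Lss, which encodes lanosterol synthase, passed over all genes, from 50.6 ± 3.42 to 29.4 ± 1.17 CPM, a log2 fold change of -0.78 (SE 0.11, adjusted p = 0.0313). Adjusted over the list alone, 6 members were lower. The other 21 did not pass, among them Cyp51 at -1.21 (adjusted p = 0.0703) and Idi1 at -1.13 (adjusted p = 0.0577). The size depends on normal gravity replicate 1: without it the median was -0.30, with 10 members lower and 1 higher (camera adjusted p = 0.000527; adjusted p = 0.407 with an estimated correlation).

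Cpt1a, which encodes the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, rose from 63.0 ± 10.9 to 154.1 ± 6.98 CPM, a log2 fold change of 1.29 (SE 0.16, adjusted p = 0.0194). It was the only 1 of 24 tested fatty acid oxidation genes to pass, also when adjusted over the list alone, and the list did not pass as a group (median -0.11, camera adjusted p = 0.537), while 7 were higher and 4 lower without normal gravity replicate 1. None of 24 fatty acid and triglyceride synthesis genes passed in edgeR or limma-voom, 1 was higher in DESeq2, and 2 were higher at an unadjusted p under 0.05 (median 0.01, camera adjusted p = 0.986), and none when adjusted over the list alone, while 6 were higher and 2 lower without that replicate 1. Fasn, the fatty acid synthase gene, stood at 247.8 ± 91.6 CPM at normal gravity and 195.9 ± 18.2 in simulated microgravity (log2 fold change -0.34, SE 0.29, adjusted p = 0.647). Srebf1, which encodes a sterol regulatory element binding protein and overlaps Rai1 on the other strand, differed by -0.21 (SE 0.10, adjusted p = 0.400) and Pparg by 0.93 (SE 0.72, adjusted p = 0.607). In the comparison without that replicate 1, Fasn was lower at -0.61 (adjusted p = 0.00328) and Pparg higher at 2.21 (adjusted p = 0.00703). Ppara had 0 counts in all 6 libraries, which allows at most 0.0154 CPM over their 194666094 counts. The same holds for Mtnr1a and Mtnr1b, the melatonin receptor genes.

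Mitochondrially encoded genes took 5.42% ± 0.94 (SD, n = 3) of the counts at normal gravity and 6.05% ± 0.19 (SD, n = 3) in simulated microgravity. The difference of 0.625 percentage points was smaller than the spread at normal gravity (exact two-sided permutation test, p = 0.3, where 0.1 is the smallest p that 3 against 3 allows), and it was 0.084 points without replicate 1, whose share was 4.34%. None of the 13 mitochondrially encoded protein genes passed in edgeR or limma-voom, 1 was higher in DESeq2 and 1 at an unadjusted p under 0.05 (median log2 fold change 0.03, camera adjusted p = 0.503), while 1 was higher and 5 were lower without replicate 1 (median -0.09, camera adjusted p = 0.284). The nuclear genes of respiratory complex I had a median of -0.26 with all 36 below 0 (camera adjusted p = 0.0045; adjusted p = 0.783 with an estimated correlation), and none passed singly in edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05. Without replicate 1 that median was 0.07 (adjusted p = 0.405), with Ndufa1 and Ndufb9 higher and Ndufs1 lower. Complexes II to V had a median of -0.21 over 40 genes (camera adjusted p = 0.000364; adjusted p = 0.747 with an estimated correlation) and 0.04 without replicate 1 (adjusted p = 0.97), where 4 members were higher and 5 lower. With all libraries Cox7a2l was the 1 member to pass, 2 were lower in DESeq2 and 3 at an unadjusted p under 0.05, and Cox7a2l passed without replicate 1 as well (-2.16, adjusted p = 0.000205).

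Citric acid cycle genes were lower with and without that library. Their median was -0.17 over 18 genes, 17 of them below 0 (camera adjusted p = 0.0045; adjusted p = 0.596 with an estimated correlation), and -0.19 without replicate 1 (adjusted p = 0.00131; adjusted p = 0.499 with an estimated correlation), where 9 fell and none rose. In the main comparison none passed over all genes, 1 was lower when adjusted over the list alone, in DESeq2 and at an unadjusted p under 0.05, and none passed in limma-voom. Genes of the mitochondrial ribosome and protein import had a median of -0.30 over 32 genes (camera adjusted p = 1.35e-07; adjusted p = 0.685 with an estimated correlation) and -0.20 without replicate 1 (adjusted p = 0.000226; adjusted p = 0.407 with an estimated correlation), where 14 fell and none rose. None passed singly with all libraries in edgeR or limma-voom, 8 were lower in DESeq2 and 13 at an unadjusted p under 0.05. Of 26 genes of mitochondrial dynamics and turnover, none passed in edgeR or limma-voom, 1 was higher in DESeq2, and 2 were higher and 1 lower at an unadjusted p under 0.05 (median -0.02, camera adjusted p = 0.861), whereas 6 were higher and 3 lower without replicate 1. Ppargc1a, which encodes a coactivator of mitochondrial biogenesis, stood at 27.1 ± 12.3 CPM at normal gravity and 42.8 ± 0.90 in simulated microgravity (log2 fold change 0.66, SE 0.36, adjusted p = 0.444; 0.33 and adjusted p = 0.0182 without replicate 1). Adjusted over the list alone, 1 gene of mitochondrial dynamics was higher, 1 of complexes II to V was lower, and none passed among mitochondrially encoded, complex I or mitochondrial ribosome genes.

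Cell cycle genes ranked below the other genes in the camera test with the preset correlation. As a group they did not pass in fry (adjusted p = 0.0584, and 0.00667 without normal gravity replicate 1). Their median was -0.35 over 40 genes, 37 of them below 0 (camera adjusted p = 1.35e-07; adjusted p = 0.596 with an estimated correlation). None passed over all genes in edgeR or limma-voom, 10 were lower in DESeq2, 17 at an unadjusted p under 0.05 and 4 when adjusted over the list alone. Leaving out normal gravity replicate 1, 35 fell and 1 rose with a median of -0.47 (adjusted p = 0.447 with an estimated correlation), including the topoisomerase gene Top2a at -0.69 (adjusted p = 0.000252) and the cyclin gene Ccnd1 at -1.53 (adjusted p = 0.00022), and the 1 that rose was Myc at 0.56 (adjusted p = 0.00442). Cytosolic ribosomal protein genes, which took the larger share of counts in replicate 1, had a median of -0.46 over 41 genes (camera adjusted p = 4.36e-07; adjusted p = 0.747 with an estimated correlation) and -0.09 without it (adjusted p = 0.0101; adjusted p = 0.792 with an estimated correlation), where 13 fell and none rose. With all libraries none of them passed in edgeR or limma-voom, 2 were lower in DESeq2, 3 at an unadjusted p under 0.05 and none when adjusted over the list alone.

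Autophagy and lysosome genes ranked above the other genes in the camera test with the preset correlation. In fry the list did not pass (adjusted p = 0.0836, and 0.00408 without normal gravity replicate 1). Their median was 0.29 over 35 genes, 33 of them above 0 (camera adjusted p = 4.44e-07; adjusted p = 0.685 with an estimated correlation). Gla, the lysosomal alpha-galactosidase gene, rose from 236.2 ± 15.7 to 429.7 ± 20.5 CPM (log2 fold change 0.86, SE 0.10, adjusted p = 0.0185), and the lysosomal membrane gene Lamp2 rose by 0.65 (adjusted p = 0.035). The other 33 did not pass, and 12 were higher and 1 lower when adjusted over the list alone. With normal gravity replicate 1 left out, 29 rose and 1 fell (median 0.47, camera adjusted p = 2.81e-10; adjusted p = 0.407 with an estimated correlation), with the cathepsin genes Ctsb, Ctsd and Ctsl at 0.59, 0.67 and 0.65. Macrophage markers had a median of 0.45 in the same comparison. In the antioxidant list none of 26 genes passed in edgeR or limma-voom, 5 were higher in DESeq2, and 5 were higher and 1 lower at an unadjusted p under 0.05 (median 0.15, camera adjusted p = 0.0691, and 0.0491 without simulated microgravity replicate 1). Adjusted over the list alone, 4 were higher. Sod2, the mitochondrial superoxide dismutase gene, differed by 0.18 (SE 0.15, adjusted p = 0.634), and was higher without normal gravity replicate 1 at 0.35 (SE 0.05, adjusted p = 0.00411). Without replicate 1, 14 antioxidant genes were higher and 2 lower (median 0.30, camera adjusted p = 0.00106; adjusted p = 0.407 with an estimated correlation), including the heme oxygenase gene Hmox1 at 1.03 (adjusted p = 0.000166).

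Of 16 tested circadian clock genes, Bhlhe41, Bhlhe40 and Per2 rose, by 1.53 (SE 0.15, adjusted p = 0.0108), 1.02 (adjusted p = 0.0131) and 1.07 (adjusted p = 0.0169) log2 units, and 13 did not pass. All 3 encode transcriptional repressors of the clock. Bhlhe41 did not pass once trends on gene length and GC content were removed (adjusted p = 0.0506), a fit chosen after seeing the data. The median was 0.29 (camera adjusted p = 0.00073; adjusted p = 0.596 with an estimated correlation), and 6 were higher when adjusted over the list alone and in DESeq2. Leaving out normal gravity replicate 1, 7 were higher and none lower (camera adjusted p = 0.00124; adjusted p = 0.407 with an estimated correlation). Of 18 immediate early genes 1 passed, the transcription factor gene Klf4, from 18.5 ± 8.27 to 126.0 ± 5.89 CPM (log2 fold change 2.77, SE 0.32, adjusted p = 0.0169). The median of that list was 0.29 (camera adjusted p = 0.0045; adjusted p = 0.747 with an estimated correlation), and 3 were higher and 1 lower when adjusted over the list alone. This list did not pass without normal gravity replicate 2 (camera adjusted p = 0.0907) or replicate 3 (0.0878). Without normal gravity replicate 1, where Fos and other members were high, 16 immediate early genes rose and 1 fell with a median of 0.81 (adjusted p = 0.407 with an estimated correlation), among them Nr4a1 at 3.86 and Fos at 1.59, which stood at -0.11 with all libraries.

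In the remaining lists no group shift passed with all libraries. Pdk1, the pyruvate dehydrogenase kinase gene held by both the glycolysis and the hypoxia list, fell from 62.9 ± 3.76 to 38.5 ± 1.34 CPM (log2 fold change -0.71, SE 0.11, adjusted p = 0.0379). It was the only member to pass of 20 glycolysis genes (median -0.10, camera adjusted p = 0.102, and 0.0477 without normal gravity replicate 3) and of 19 hypoxia genes (median -0.05, camera adjusted p = 0.915). Cxcl10, an interferon-induced chemokine gene, fell from 45.3 ± 4.19 to 14.8 ± 1.83 CPM (log2 fold change -1.62, SE 0.15, adjusted p = 0.0079), alone among 26 interferon response genes (median 0.21, camera adjusted p = 0.418). The cytokine gene Lif rose from 25.2 ± 0.17 to 61.4 ± 1.28 CPM (log2 fold change 1.28, SE 0.10, adjusted p = 0.00513), alone among 22 NF-kB and cytokine genes (median -0.06, camera adjusted p = 0.355), of which 1 was higher and 6 were lower when adjusted over the list alone. None passed in edgeR or limma-voom among 27 genes of the unfolded protein and integrated stress response (camera adjusted p = 0.695), 23 of extracellular matrix and adhesion (0.644), 25 of the actin cytoskeleton and YAP/SRF targets (0.727), 25 apoptosis and p53 targets (0.213) and 12 heat shock genes (0.855). At an unadjusted p under 0.05 these lists had 5, 8, 6, 6 and 0 higher members and 1, 5, 1, 3 and 3 lower members, and in DESeq2 3, 5, 1, 4 and 0 higher and 1, 2, 1, 3 and 1 lower. Adjusted over the list alone, they had 3, 5, 0, 4 and 0 higher and 1, 2, 0, 3 and 0 lower members. Over their own lists, glycolysis had 0 and 2, hypoxia 1 and 1 and interferon response 2 and 1. More members passed without normal gravity replicate 1. The unfolded protein response had 11 higher and 6 lower, extracellular matrix 5 and 5, actin and YAP/SRF targets 8 and 5, apoptosis and p53 targets 10 and 4 and heat shock 1 and 4. Glycolysis had 4 and 4, hypoxia 5 and 3, interferon response 5 and 2 and NF-kB 8 and 8.

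**Figure D3:**
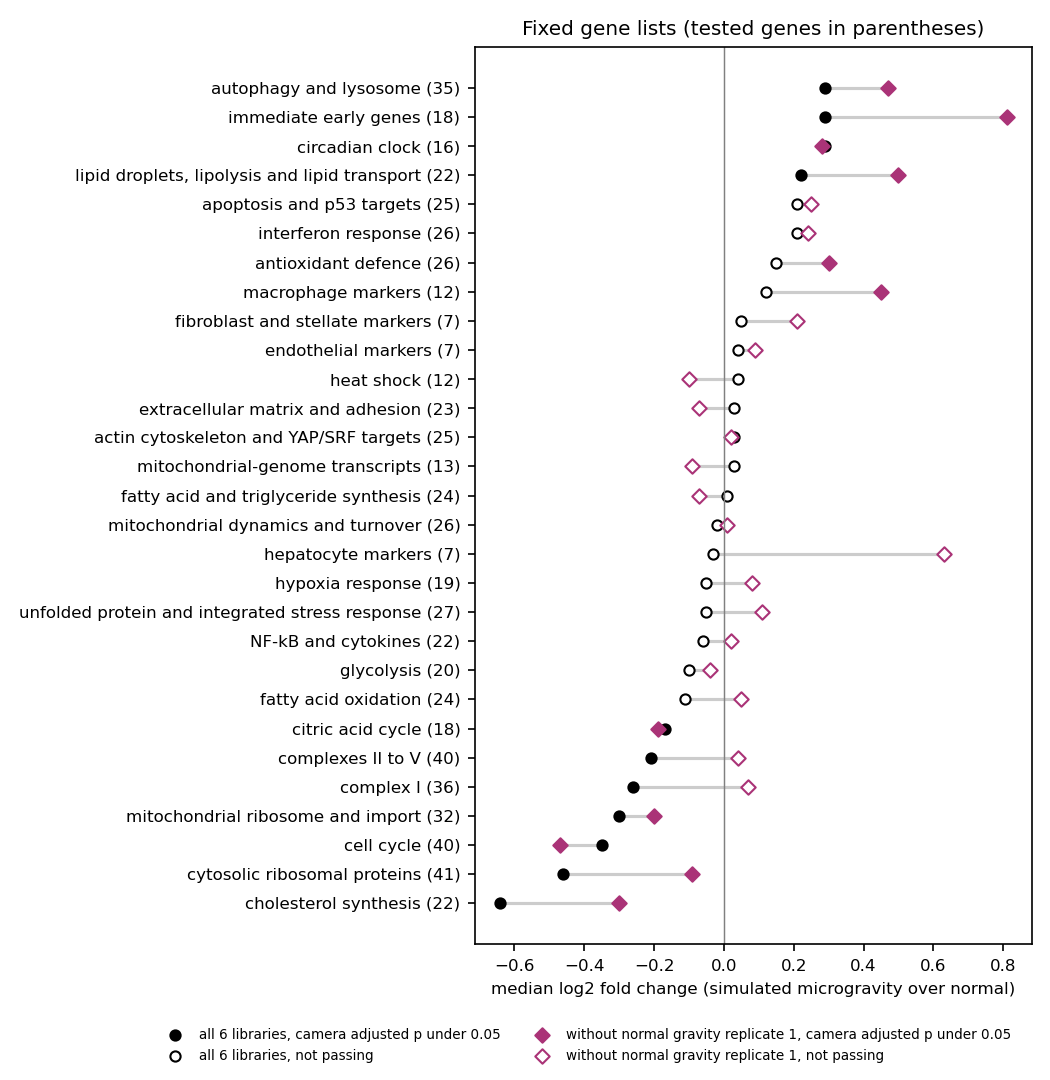
Median log2 fold change of each fixed list with at least 5 tested genes, with all 6 libraries (black circles) and without normal gravity replicate 1 (purple diamonds); filled marks had a camera adjusted p under 0.05. Cholesterol synthesis lies lowest at -0.64 with all libraries and at -0.30 without replicate 1, while complex I crosses 0 from -0.26 to 0.07.

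Several markers of macrophages were abundant in every library and most markers of hepatocytes were not detected. Of 35 hepatocyte marker genes, 23 had 0 counts in all 6 libraries, among them Alb, Hnf4a, Krt8, Krt18 and Apob, each of which could be at most 0.0154 CPM. Of 7 that could be tested, Ass1, which encodes argininosuccinate synthase of the urea cycle, rose from 114.9 ± 13.7 to 234.0 ± 21.5 CPM (log2 fold change 1.03, SE 0.13, adjusted p = 0.0247), and 6 did not pass (list median -0.03, camera adjusted p = 1; 3 higher and 2 lower without normal gravity replicate 1). Of 17 macrophage markers, 9 had a mean of at least 100 CPM, while 5 were below 1 CPM, 1 of these with 0 counts in all libraries. Csf1r, the receptor gene for macrophage colony-stimulating factor, stood at 2118 to 2281 CPM at normal gravity and 2459 to 2526 CPM in simulated microgravity. The lysozyme gene Lyz2 stood at 3928, 969 and 1022 CPM in the normal gravity libraries and 3516 to 4558 CPM in simulated microgravity. None of 12 tested macrophage markers passed in edgeR or limma-voom, 2 were higher in DESeq2 and 3 at an unadjusted p under 0.05 (median 0.12, camera adjusted p = 0.176). Once normal gravity replicate 1 was left out, 7 of 13 were higher and none lower (median 0.45, camera adjusted p = 0.0101; adjusted p = 0.407 with an estimated correlation), with Marco at 3.67 and Lyz2 at 2.07. Among 7 tested fibroblast and stellate cell markers Pdgfrb rose by 1.36 (SE 0.21, adjusted p = 0.0396) from 2.27 ± 0.40 CPM, and among 7 endothelial markers Vwf rose by 1.62 (SE 0.15, adjusted p = 0.00886) from 16.5 ± 1.12 CPM. Neither list passed (camera adjusted p = 0.243 and 0.507). Adjusted over the list alone, 1 hepatocyte marker was higher and 1 lower, 1 fibroblast and 1 endothelial marker were higher, and no macrophage marker passed. Too few genes for a list test were expressed among cholangiocyte markers (1 of 12, Spp1, at -0.83 and adjusted p = 0.088), lymphocyte and erythroid markers (2 of 15) and adipocyte and muscle markers (2 of 13).

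**Figure D4:**
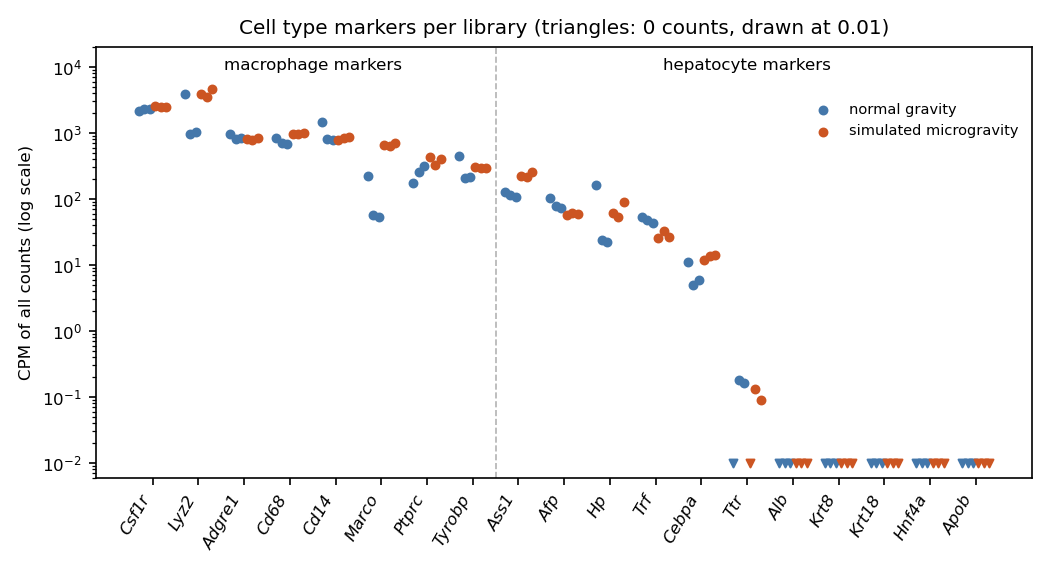
CPM of all counts on a log axis for 8 macrophage and 11 hepatocyte marker genes, with 1 point per library (blue normal gravity, orange simulated microgravity); triangles at 0.01 stand for 0 counts. Csf1r lies at 2118 CPM or above in each library, while Alb, Krt8, Krt18, Hnf4a and Apob have 0 counts in all 6.

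Pathway terms that the deposited table assigns to its genes gave 43 of 316 past the threshold, 18 higher and 25 lower. The 5 lowest adjusted p among lower terms belonged to ribosome biogenesis (80 genes, median -0.22, camera adjusted p = 0.00023), DNA replication (38 genes, -0.28, 0.00023), base excision repair (58 genes, -0.26, 0.00045), pyrimidine metabolism (95 genes, -0.23, 0.00045) and the spliceosome (203 genes, -0.15, 0.00045). Among higher terms they belonged to sphingolipid metabolism (33 genes, 0.27, 0.000354), the lysosome (117 genes, 0.18, 0.000603), the term autophagy in other organisms (33 genes, 0.12, 0.00529), collecting duct acid secretion (18 genes, 0.31, 0.00709) and the synaptic vesicle cycle (43 genes, 0.18, 0.00709). With an estimated correlation no term passed, the lowest adjusted p being 0.482. In the comparison that left out normal gravity replicate 1, 25 of the 43 terms passed in the same direction, these 10 among them.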

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

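The fits with library quality weights and with gene length or GC trends removed were chosen after the data were seen. Of the 221 genes, 202 to 218 were called again with DESeq2 size factors, library size alone, limma-voom, the 1 CPM filter or thinned counts, and all 221 in DESeq2, which called 1230 (714 higher, 516 lower), and without mitochondrially encoded genes. In simulated counts where 20 genes were shifted by 0.5 log2 units, DESeq2 called 26 genes and edgeR 0. The 26 exceed the 20 shifted genes, so some of them were unchanged genes. How many of the 20 were among them was not counted, so these counts do not show which tool was nearer the truth. Without a filter 125 were called (102 higher, 23 lower) and 18 pathways passed, and of the named genes Tppp3, Lss, Pdk1, Pdgfrb and Cd36 lost their calls (adjusted p from 0.0501 for Cd36 to 0.0664 for Tppp3). Against a fold of 1.5, 52 were called (39 higher, 13 lower). With library quality weights, where normal gravity replicate 1 weighs 0.0506 and the other libraries 1.38 to 2.25, the count was 4798 (2525 higher, 2273 lower). With the length trend removed it was 696 (439 higher, 257 lower) with 28 pathways, and with length and GC trends removed 905 (561 higher, 344 lower) with 28 pathways, and the share of higher genes was 52.6%, 63.1% and 62% in these 3 fits. Leaving out 1 library gave 3 to 4559 genes (3 to 2329 higher, 0 to 2230 lower), 10 to 12 lists and 22 to 40 pathways, and a mitochondrial share difference of 0.084 to 0.931 points. The highest gene and pathway counts came without normal gravity replicate 1 and the highest list count without simulated microgravity replicate 1. Without normal gravity replicate 1 the biological coefficient of variation was 14.3% against 27.9%. The count of 0 lower genes came without simulated microgravity replicate 1, where 3 genes were called and 1446 had an unadjusted p under 0.05. The cause of these changes was not tested.

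With an estimated correlation 0 lists and 0 pathways passed, and in fry 4 lists did: citric acid cycle, circadian clock, lipid droplets and transport, and endothelial markers. No pairing of the samples by replicate number showed. The deviations of same-numbered libraries from their group means correlated at -0.07, 0.02 and -0.09, and not every library correlated best with its own number. Pairing cannot be excluded in this way, since normal gravity replicate 1 stands apart and enters the mean of its group. With the replicate block edgeR called 0 genes (0 higher, 0 lower), and 1534 had an unadjusted p under 0.05. The block leaves fewer residual degrees of freedom. No named gene changed direction, and 11 lists and 35 pathways passed in camera with the preset correlation. The mitochondrial difference is 0.625 points by construction, since a balanced block cannot change it. DESeq2 and limma-voom were not run with the block.

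The calls of complexes I and II to V were lost with quality weights and that of complex I with both trends removed (adjusted p = 0.0504), while antioxidant defence passed in the 3 fits chosen later. Some main lists that did not pass had a mean log2 fold change, relative to all genes, whose sign turned, and none of these passed in either fit. Fatty acid oxidation was at 0.03 without a filter, 0.04 with quality weights and -0.11 to 0.01 (the latter without normal gravity replicate 1) with 1 library left out. Extracellular matrix was at -0.24 without a filter, -0.14 with the 1 CPM filter, -0.02 thinned, -0.06 without normal gravity replicate 3, -0.02 without simulated microgravity replicate 3, up to 0.15 with another library left out and -0.06 in both trend-corrected fits. The unfolded protein response was at -0.08 without a filter, -0.03 without normal gravity replicate 2, -0.05 without replicate 3 and up to 0.13 without another library. Hypoxia was at 0.08 with the 1 CPM filter, -0.08 to 0.06 with 1 library left out (0.06 without normal gravity replicate 1), 0.04 without simulated microgravity replicate 1 and 0.06 with quality weights. Mitochondrial-genome transcripts were at -0.14 without normal gravity replicate 1, up to 0.18 without another library and -0.12 with quality weights. Median and mean differed in sign for mitochondrial dynamics (-0.02 and 0.06), the unfolded protein response (-0.05 and 0.02) and heat shock (0.04 and -0.04), and for hepatocyte markers both lay below 0 while the test pointed up.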

Other observations

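The tests of gene length, of gene length with GC content and of a label swap for normal gravity replicate 1, that of lost genes in this library, that of mixed-in macrophages and the splits of 5 libraries were chosen after the results were seen. Of the genes called outside the fixed lists, 4 are given as single values, chosen after their values were seen and not as a group. The small GTPase gene Rhob rose by 2.51 log2 units (SE 0.11, edgeR adjusted p = 0.00136), the sphingomyelin synthase gene Sgms2 by 1.83 (SE 0.10, adjusted p = 0.00282) and Igf1 by 1.22 (SE 0.18, adjusted p = 0.0355). The chemokine gene Ccl22 had a log2 fold change of -4.23 (SE 0.37, adjusted p = 0.00733), from 3.18 CPM at normal gravity. Median log2 differences between simulated microgravity and normal gravity replicates 2 and 3 lay between -0.07 on chromosome X and 0.05 on chromosome 7.

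Normal gravity replicate 1 lies away from replicates 2 and 3, and its deviation falls with gene length (Spearman rho across genes -0.50) and rises with GC content (0.35). Removing the length trend lowered its SD from the other 2 libraries from 1.00 to 0.91, and removing both trends lowered it to 0.87, against at most 0.45 for a microgravity library, which argues against either trend as the whole cause. Replicate 1 correlated better with each microgravity library (0.943 to 0.946) than with its own group (0.936), but a swap with a microgravity library would need 1 that correlates better with normal gravity replicates 2 and 3 than with its own group, and each correlated better with its own group by at least 0.0136. A state of that culture shared in part with the microgravity libraries stays open, since its test, a correlation across genes of replicate 1 minus replicate 2 with simulated microgravity minus replicate 3 (r = 0.31), puts the common state of replicates 2 and 3 into both differences. So do a wrong label with no partner in this series and a difference in RNA handling, both untested.

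In 19 genes 1 library of a group was below 1 CPM while another of the same group had at least 20 CPM. Of these, 15 were lowest or tied for lowest in normal gravity replicate 1, the ties being Gm20716 and AC034099.1 at 0. Division of reads between overlapping genes may explain some of them: 73.7% overlap another expressed gene, against 21.6% of 190 genes of matched expression (Fisher's exact test, odds ratio 10.03, 95% confidence interval 3.18 to 37.7), and for 9 of the 14 with such a partner the summed CPM differed by less than 2-fold. An abundant partner keeps the sum within 2-fold even where no reads moved, and no matched genes were summed, so the sums cannot decide this. The matched genes are shorter (median 3463 against 5288 bases), and length was not matched. The length trend of replicate 1 does not account for the 15, whose median deviation was -6.44 log2 units as deposited and -5.93 with the trend removed. None of the 19 is among the 221 genes called, and no biological explanation was tested.

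The abundance of several macrophage markers with few hepatocyte markers holds in each of the 6 libraries. Hepatocytes that express Alb, Krt8, Krt18 and Hnf4a would leave these transcripts in a mixture with macrophages. These genes together had 0 of 194666094 counts, which argues against such hepatocytes in the cultures. Macrophages mixed with cells that have lost these genes would also give 0, so the test cannot speak to that mixture. Of 35 hepatocyte markers, 5 had a mean of at least 10 CPM. Gene names paired with the wrong identifiers are argued against as well, since 0 of the 52 hepatocyte and macrophage markers carry another symbol in the reference annotation. A line that has lost hepatocyte expression would lack the hepatocyte markers. That loss alone would not give 9 of 17 macrophage markers a mean of at least 100 CPM. Such a line and a culture of another origin than its label both stay open, since no library of a reference culture was analysed here.

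A hypothesis on lipids was that liver X receptors, which activate Abca1 and Abcg1, were more active in simulated microgravity. It was tested on 11 other target genes, of which 7 were expressed. Without normal gravity replicate 1 their median log2 fold change was 0.21, below the 0.3 set in advance for it and above the 0.1 set against it, so the test leaves the hypothesis open, although the other part of its prediction, a p under 0.05 in limma's camera test of this 1 list, was met (adjusted p = 0.0315 over 1 list, and 0.0863 with all libraries). That camera test used the preset correlation, and an estimated correlation was not applied to this list. Without normal gravity replicate 1, Pltp at 1.56 (edgeR adjusted p = 0.000419) and Arl4c at 0.77 (edgeR adjusted p = 0.000571) were higher. None of the other 5 passed, and of these Lpcat3 lay below 0 at -0.15 and the rest above 0. With all libraries the median was 0.28. The result holds for the 7 tested genes only. The lipid genes Srebf1, Fasn and Lpl were not among them. All had log2 fold changes below 0 with all libraries, opposite in direction to Abca1 and Abcg1, and only Lpl passed. Without normal gravity replicate 1, Srebf1 stood at -0.17 (edgeR adjusted p = 0.094) and Fasn at -0.61 (edgeR adjusted p = 0.00328).

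Other groupings of the 6 libraries into 3 and 3 make 10 splits with the real one, too few for a share under 0.05. The real split called 221 genes and the highest other 1, with 1 split as large, the real one included. It gave 43 pathways against at most 34 in another split, with 1 as large, and 11 lists against 12, with 3 as large. Without normal gravity replicate 1, the 10 splits of the other 5 libraries gave at most 6 genes, 11 lists and 22 pathways apart from the real one, which gave 4559, 11 and 40. Those that kept normal gravity replicates 2 and 3 on the same side gave 7 to 11 lists, and those that parted them 0 or 1.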
